A study of Homo sapiens with 8 samples.

How the data were processed

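Gene expression was measured on single-channel arrays hybridised with biotin-labelled RNA from the human prostate cancer cell line DU145 and from 7 sublines of it, with 1 array per line. Per the labels' protocols, total RNA was extracted from the cells on RNeasy columns and labelled as the manufacturer instructs. The lines were grouped from the labels into 1 parental line, 3 sublines recovered from lymph node metastases of prostate xenografts after 1, 2 and 4 rounds, and 4 sublines recovered from lung metastases after tail vein injection, after 1, 2, 3 and 4 rounds.

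The deposited table holds a probe intensity on a linear scale for each of 12660 probes on each array. The scanner, the software, the normalization and any probe filter are not given in the sources used here. Values below 0 occur on every array, as background subtraction would leave them, and array medians lay close together, but no source used here states how the values were made comparable. Highest values differed between arrays, from 42589 to 73475 intensity units, so the arrays do not share 1 distribution. Detection calls were not analysed here, so no probe is called present or absent. The number of arrays limits the precision, and no batch, slide or date was given in the sources used here.

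Probes carry identifiers built from a GI number, the former serial number of NCBI sequence records, with the ending S (10276 probes), A (1380 probes) or I (1004 probes). None of the 12494 GI numbers matched a gene ID or synonym in the gene table used here, so 0 probes have a gene name, and results are given by probe identifier. For the same reason none of the 29 gene lists planned, which covered pathways and markers of other cell types, could be tested, and their set tests were not run. RNA of other cell types was therefore not looked for.

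Values below 0 were set to 0, 16 was added, and log2 was taken. Differences are therefore on the log2(intensity + 16) scale, which understates changes of dim probes. Median log2 values differed between arrays by at most 0.059, under the limit of 0.1 set in advance, and the deposited scaling was kept. Probes whose mean log2 value over all 8 arrays lay above the 30th percentile of probe means were tested, which left 8862 probes with mean values above 6.22.

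Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. A model of group means over all 8 arrays, with 5 residual degrees of freedom, gave lung against lymph node sublines and each route against the parental line. The single parental array was assumed to vary like the subline groups. A second model, with an intercept and the number of rounds in each route (parental line at 0 in both), gave a slope per round for each route and their difference. The labels number each array as replicate 1 of its line. The sublines of a route are numbered by successive rounds and are not stated to be separate derivations, so p-values measure only the spread between these lines.

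Probes to be named were chosen by a rule. The tests, this rule, the gene lists and the alternatives below, unless said otherwise, were fixed before the data were examined. For lung against lymph node they are the largest differences past the threshold whose groups do not overlap. Against the parental line every subline of the route had to lie at least 1 log2 unit away on one side. For a slope, values had to follow the order of the rounds from the parental line on. Where no probe passed, the largest differences that met the other condition were taken. Without gene names, at most 2 probes per direction were named for each comparison.

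Changes of single lines from the parental array were counted at 2-fold without a test. Because all such changes share 1 parental array, the same counts were simulated for 8 lines that differ only by the fitted spread (100 draws). The correlation of both routes' changes from the parental line was simulated in the same way (1000 draws). The fitted spread includes any change between the rounds of a route, so these simulated lines may vary by more than array noise. The model fits were tested on simulated data for the same 8862 probes with 200 changed probes, in 10 simulations per comparison. For lung against lymph node, 78% of changes of 1 log2 unit and 98.8% of changes of 2 log2 units were recovered, and 6.75% of the calls were false. Against the parental line, 36.9% and 89.1% were recovered for the lymph node route and 35.7% and 90.2% for the lung route. For the lung slope, 92.1% of slopes of 0.5 log2 units per round were recovered.

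Alternatives were quantile normalization, median centring, no filter or a filter at the 50th percentile, a pseudocount of 1 or 64, a constant variance prior, only the arrays of the groups compared, the number of rounds as a block, a 2-fold minimum, slopes over the sublines of a route alone, and leaving out each array in turn. Cyclic loess normalization and a slope with lung rounds 3 and 4 exchanged were added after seeing the data, as were the repeats of the slope difference between the routes. No array pair held identical values: at most 18 of 12660 probes had the same intensity on any 2 arrays. Figures were drawn with matplotlib 3.10.9.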

Results

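Expression was compared between DU145, a human prostate cancer line, and sublines of it selected in vivo for metastasis to lymph node (DU145-LN1, DU145-LN2 and DU145-LN4, n = 3 lines) or to lung (DU145ivLU1 to DU145ivLU4, n = 4 lines). The number in each name is the number of rounds of selection. Each line was measured on 1 array, and 8862 probes were bright enough to be tested. Median intensity was lowest in DU145ivLU4, at 156.8, and highest in the parental line. Values below 0 made up 0.142% of probes on the parental array, between 1.22% and 2.50% on 6 subline arrays, and 4.12% on the DU145ivLU3 array. Probes are named by identifier because they could not be paired with genes here.

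The first question was how far each subline had moved from the parental line. In the lymph node route the number of probes at least 2-fold from the parental array went from 189 in DU145-LN1 to 376 in DU145-LN2 and 556 in DU145-LN4. In the lung route it was 253 in DU145ivLU1, 364 in DU145ivLU2, 1173 in DU145ivLU3 and 643 in DU145ivLU4. DU145ivLU3 thus had 13.2% of the tested probes 2-fold from the parental line, more than any other subline, and 201 probes were at least 4-fold away, against 96 in DU145ivLU4 and 75 in DU145-LN4. Higher and lower probes were both frequent, with 563 higher and 610 lower in DU145ivLU3 and 283 higher and 273 lower in DU145-LN4. These counts have no replicate check. Of all arrays, the parental one had the narrowest range of intensities and the fewest values below 0. The DU145ivLU3 array had the widest range and the most values below 0. Whether this contrast between the arrays adds to the count of DU145ivLU3 was not tested. Lines differing only by the fitted spread between lines would give 220 probes per line on average, near the counts of DU145-LN1 and DU145ivLU1. That spread includes any change between the rounds of a route, so 220 is not a level of array noise alone.

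**Figure D1:**
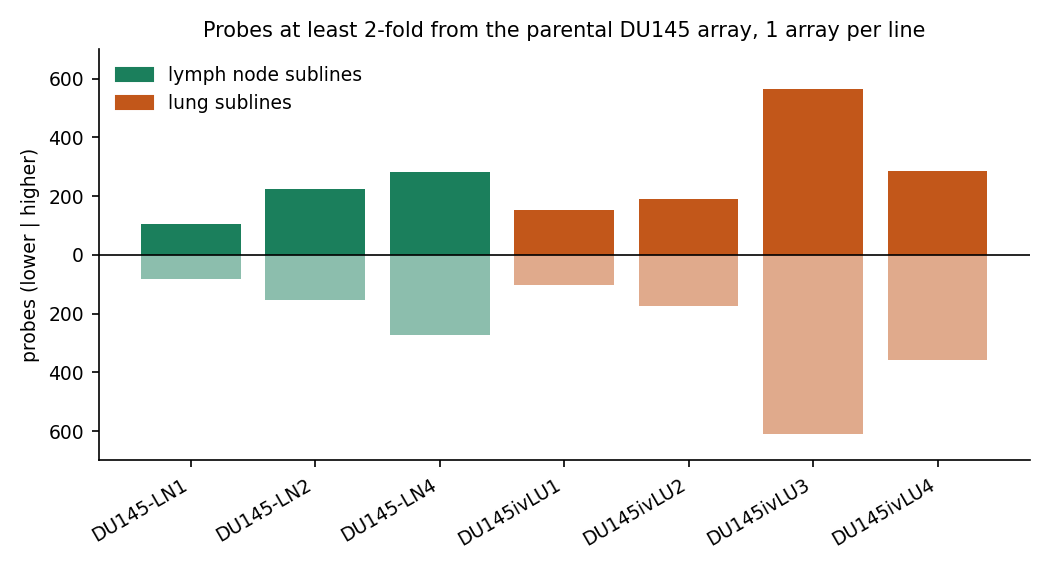
Number of probes at least 2-fold higher (solid bars, upward) or lower (pale bars, downward) than on the parental DU145 array, for each subline, out of 8862 probes tested. DU145ivLU3 has 563 higher and 610 lower probes, and the lymph node lines go from 189 to 556 probes in all.

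Along the lymph node route, probes 2-fold higher in an early line mostly stayed so. Of the 106 probes higher in DU145-LN1, 86 were also higher in DU145-LN2 and 89 in DU145-LN4. Of the 83 probes lower in DU145-LN1, 50 were lower in DU145-LN2 and 50 in DU145-LN4. Along the lung route, 97 of the 151 probes higher in DU145ivLU1 were higher in DU145ivLU2 and 76 in DU145ivLU4. For the 102 probes lower in DU145ivLU1 the counts were 60 in DU145ivLU2 and 47 in DU145ivLU4. Of the 563 probes higher in DU145ivLU3, 211 were higher in DU145ivLU4, and of the 610 lower ones 261 were lower there. Independent lists would share 2.67 higher probes between DU145-LN1 and DU145-LN2, 3.22 between DU145ivLU1 and DU145ivLU2 and 18.0 between DU145ivLU3 and DU145ivLU4. Every change was taken against the same parental array. Lines simulated with the fitted spread alone, with lists of about equal length, shared 29.0% of their higher probes on average. Part of each overlap may therefore come from that array.

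Early lines of one route lay closer to each other than to the other route. The root mean square log2 difference was 0.312 between DU145-LN1 and DU145-LN2, 0.294 between DU145-LN2 and DU145-LN4, and 0.288 between DU145ivLU1 and DU145ivLU2. Between the routes at the same round it was 0.503 after 1 round, 0.548 after 2 rounds and 0.625 after 4 rounds. Within the lung route the distances from the first 2 lines to the later ones were larger, at 0.494 from DU145ivLU2 to DU145ivLU4, 0.630 from DU145ivLU2 to DU145ivLU3, 0.689 from DU145ivLU1 to DU145ivLU3 and 0.540 from DU145ivLU1 to DU145ivLU4. DU145ivLU3 and DU145ivLU4 differed by 0.423. The first principal component held 43.6% of the variance and separated DU145ivLU3 and DU145ivLU4 from the other 6 lines, and the second held 26.4% and separated DU145ivLU1, DU145ivLU2 and the parental line from the other 5 lines.

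**Figure D2:**
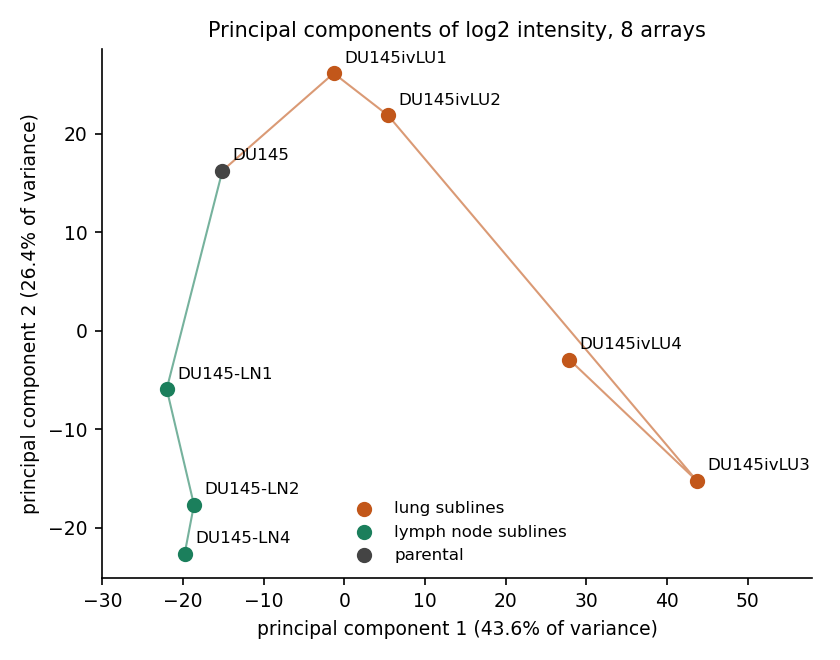
First and second principal components of log2 intensity over 8862 probes, 1 point per array, with lines joining each route in the order of its rounds from the parental line. The lymph node lines run in order of their rounds on the second component only, and DU145ivLU3 lies farther from the parental line than DU145ivLU4.

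The main comparison, lung against lymph node sublines, asked which transcripts separate the sites and routes of selection. In limma, 1209 of 8862 probes (13.6%) passed an adjusted p of 0.05, with 625 higher and 584 lower in the lung sublines. Among these, 121 were at least 2-fold higher and 150 at least 2-fold lower, and 12 and 21 were at least 4-fold higher and lower. The median size of the differences that passed was 0.72 log2 units. Groups did not overlap on any array for 30.1% of the tested probes, where lines independent of each other would give 5.71%. Sublines of a route may share descent, which also keeps groups apart, so 5.71% is not a baseline for these lines. Of the probes past the threshold, 622 of the 625 higher and 583 of the 584 lower ones had groups that did not overlap. The call, made on the same arrays, favours such probes.

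The largest rise in the lung sublines was that of GI_4504936-S, at 10.50 ± 0.45 (SD, n = 4) log2 units in lung and 6.32 ± 1.25 (SD, n = 3) in lymph node lines, a difference of 4.17 with a standard error of 0.51 (limma adjusted p = 0.00336). Its intensity was 134.8 in the parental line and between 986.4 and 1961.8 in the lung lines. GI_6006000-S was higher in lung by 3.48 log2 units (SE 0.43, limma adjusted p = 0.00356), with intensities from 365.4 to 796 in lung and from 10.8 to 85.6 in lymph node lines. GI_40788008-S was lower in lung, with a difference of -4.02 log2 units (SE 0.59, limma adjusted p = 0.00571). Its intensity was 570.2 to 854 in the lymph node lines, 385.7 in the parental line and -9.4 to 100.9 in the lung lines. GI_14574570-S differed by -3.70 log2 units (SE 0.44, limma adjusted p = 0.00336), with intensities of -0.4 to 24.8 in lung and 168.7 to 481.8 in lymph node lines. For the last 2 probes some lung values lay at or below 0, so their differences depend on the added 16 units. With 64 units added, the difference of GI_14574570-S was -2.38.

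**Figure D3:**
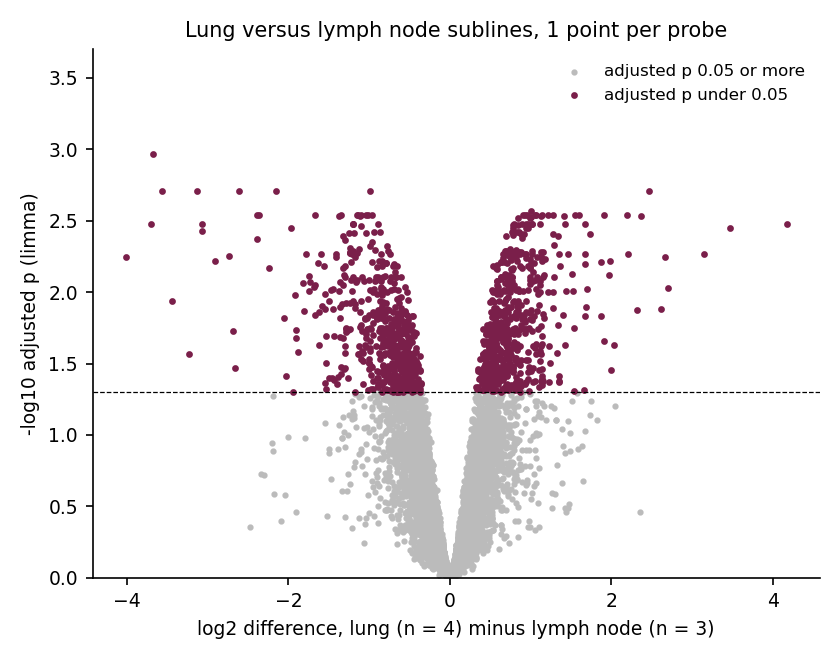
Log2 difference of lung (n = 4) minus lymph node (n = 3) sublines on the horizontal axis and -log10 of the limma adjusted p on the vertical axis, 1 point per probe, with the 0.05 threshold dashed. The 1209 probes past the threshold split into 625 higher and 584 lower in lung.

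The parental value was set against both group means at these probes, without a test of an even split. Of the 625 probes higher in lung, the parental value was nearer the lymph node mean for 321 and nearer the lung mean for 304. Of the 584 probes lower in lung it was nearer the lymph node mean for 337 and nearer the lung mean for 247. It lay between both means for 440 of the higher and 415 of the lower probes. The same contrast at single rounds, which share no array, gave 365 probes 2-fold apart after 1 round, 510 after 2 and 743 after 4. Across probes, the round 1 difference correlated with the round 2 difference at r = 0.684 and with the round 4 difference at r = 0.441, although probes are not independent replicates. When probes were called on the lines of 2 or more rounds alone (372 probes), 365 of them differed in the same direction between DU145ivLU1 and DU145-LN1 (98.1%, against 68.4% over all tested probes), and the median round 1 difference was 0.65 of the later one. The count of 1209 fell to 291 without DU145-LN2, 319 without DU145-LN4, 554 without DU145-LN1 and 797 without DU145ivLU2. Without DU145ivLU3 it was 1265.

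For the lymph node sublines against the parental line, 0 probes passed in limma, with a lowest adjusted p of 0.091. Unadjusted p-values were under 0.05 for 1169 probes, where 443 would be expected by chance. When the spread was taken from these 4 arrays alone, without the lung lines, 251 probes passed, 140 higher and 111 lower. In the fit with the lung lines, 4 passed when DU145-LN1 was left out. The largest differences with all 3 lines on one side were 4.87 log2 units for GI_8923166-S (SE 1.87) and 4.32 for GI_16418396-S (SE 1.65), and -3.17 for GI_38327521-S (SE 0.74) and -2.98 for GI_19747278-A (SE 1.38). Their limma adjusted p-values were 0.338, 0.338, 0.228 and 0.401. GI_8923166-S, GI_38327521-S and GI_19747278-A passed on these 4 arrays alone. GI_8923166-S read -0.3 in the parental line, so its difference is set by the added 16 units. It was 8.81 with 1 unit added and 3.02 with 64, where GI_16418396-S was larger, at 3.12, as it was with quantile normalization, at 5.12. With 64 units added the difference of GI_38327521-S was -2.02. In all, 79 probes were 2-fold above the parental value in every lymph node line and 41 were 2-fold below. Lines simulated with the fitted spread alone gave 15.1 above on average.

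For the lung sublines against the parental line, 0 probes passed in limma, with a lowest adjusted p of 0.0708 and 1433 probes at an unadjusted p under 0.05. Without DU145ivLU3, 3 probes passed, all lower. The largest differences with all 4 lines on one side were 3.36 log2 units for GI_34222365-S (SE 0.53, limma adjusted p = 0.071) and 3.26 for GI_4504936-S (SE 0.74, limma adjusted p = 0.137), and -3.18 for GI_40788008-S (SE 0.87, limma adjusted p = 0.176) and -3.08 for GI_24475622-S (SE 1.12, limma adjusted p = 0.244). GI_34222365-S read 32.6 in the parental line, 389.7 to 596 in the lung lines and 185.5 to 693.4 in the lymph node lines. Every lung line lay 2-fold above the parental value for 53 probes and 2-fold below it for 38. Lines simulated with the fitted spread alone gave 9.29 above on average and 18 at most.

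Both routes were then set against each other as changes from the parental line. Across probes these changes correlated at r = 0.492, with 68.5% of probes changed in the same direction. Both comparisons use the single parental array, and groups simulated with the fitted spread alone that share it gave r = 0.775 and 78.2%. The covariance was 0.112 against a simulated 0.0823 (95% of draws from 0.0767 to 0.0886), a difference of 0.0298. The fitted spread includes any change between the rounds of a route. The simulated values therefore do not measure the effect of the shared array alone. All 7 sublines were 2-fold above the parental array for 14 probes, where independent lists would share 0.472. The simulated lines shared 3.6 on average and 8 at most. All 7 were 2-fold below it for 2 probes. By contrast, 24 probes were 2-fold above it in every lymph node line and in no lung line, and 21 in every lung line and no lymph node line. The parental array could not be split, so part of any excess may come from that array.

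The number of rounds was tested as a slope from the parental line. In the lung route 553 probes passed in limma, 198 rising and 355 falling. With each array centred on its median the split was 265 rising and 280 falling. Values followed the order of the rounds at every step for 3.88% of all tested probes, where lines independent of each other would give 1.67%. Successive lines may share descent, so this share is no test of change in the order of the rounds. Among the probes past the threshold that followed this order, the steepest falls were those of GI_34147344-S, at -1.33 log2 units per round (SE 0.17, limma adjusted p = 0.0068), and GI_5453789-S, at -1.20 (SE 0.14, limma adjusted p = 0.00591). GI_34147344-S went from 1215.4 in the parental line to 990.4, 931.7, 94.5 and 18.8 over the 4 lung rounds and stayed between 874.4 and 1548.7 in the lymph node lines. GI_5453789-S went from 6222.4 to 4011.6, 3211.3, 337 and 283.5, with its largest log2 step between rounds 2 and 3. It also fell in the lymph node route, to 4327.2, 3025.5 and 1185.9 after 1, 2 and 4 rounds. Among the same probes the steepest rises were 0.94 log2 units per round for GI_4504936-S (SE 0.22, limma adjusted p = 0.0406) and 0.78 for GI_24497582-S (SE 0.19, limma adjusted p = 0.0418). Over the 4 lung lines alone the slope of GI_4504936-S was 0.34, and its largest step was that from the parental line to DU145ivLU1. Both rises missed the threshold without DU145ivLU3, without DU145ivLU4 or without the parental array, and that of GI_24497582-S also without DU145ivLU1. With a constant variance prior both missed it (limma adjusted p = 0.0607 and 0.0626) and 205 probes passed. The count was 266 without DU145ivLU3, 293 without DU145ivLU1 and 16 without the parental array, and 0 when the slope was fitted to the 4 lung lines alone.

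**Figure D4:**
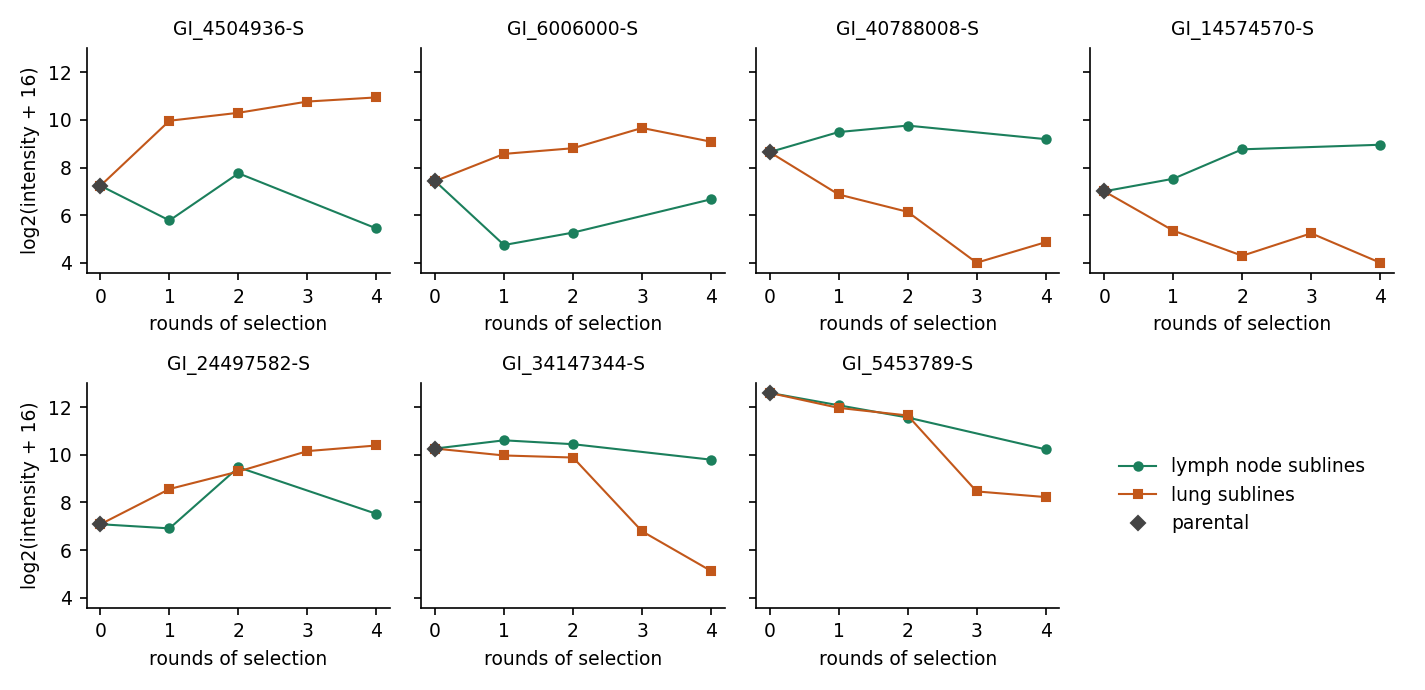
Log2(intensity + 16) against rounds of selection for the 7 probes named for lung against lymph node and for the lung slope, 1 array per point, with the parental line at 0 rounds in both routes. GI_4504936-S lies above the lymph node lines at every lung round, and GI_34147344-S and GI_5453789-S drop between lung rounds 2 and 3.

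In the lymph node route 28 probes passed the slope test, 13 rising and 15 falling, all near the threshold, with a lowest limma adjusted p of 0.0499. With median centring, a filter at the 50th percentile or a constant variance prior 0 passed, and 1 passed with a pseudocount of 64. Among those that followed the order of the rounds, the steepest rises were 1.5 log2 units per round for GI_16418396-S (SE 0.24, limma adjusted p = 0.0499) and 1.02 for GI_40254981-S (SE 0.17, limma adjusted p = 0.0499). GI_16418396-S read 14 in the parental line and 125.9, 985.8 and 1496.8 after 1, 2 and 4 rounds. The steepest falls were those of GI_6382070-I, at -0.95 (SE 0.15), and GI_6382070-A, at -0.92 (SE 0.15), which carry the same GI number and have the same limma adjusted p of 0.0499. Both rested on DU145-LN4, where they read -12.9 and -7.5 against 150.1 and 157.7 in DU145-LN2. Their slopes were -1.88 and -1.85 with 1 unit added before log2 and -0.53 and -0.50 with 64. Without DU145-LN4 their slopes were -0.27 and -0.18, and those of GI_16418396-S and GI_40254981-S were 2.54 and 1.63. All 4 named slopes missed the threshold without DU145-LN1 or without the parental array, and that of GI_40254981-S without any single lymph node line. The count was 13 without DU145-LN4, 9 without DU145-LN2, 1 without DU145-LN1 and 0 without the parental array. Over the lymph node lines alone 193 probes passed, with the 4 named slopes among them. That fit sets an intercept and a slope through only 3 arrays, which leaves little to measure the spread. The 4 probes had been chosen for following the order of the rounds on these arrays, so their passing is no separate support. Values followed the order of the rounds for 22.6% of tested probes, where lines independent of each other would give 8.33%. As in the lung route, that share is no test. Slopes differed between the routes for 1263 probes in a test of the difference itself, with 608 more positive and 655 more negative in the lung route. This count was 85 without DU145-LN4, 437 without DU145-LN2 and 773 without DU145-LN1. Both slopes start from the parental value, so a route difference present after 1 round and steady since also counts as a slope difference. The count therefore does not by itself show different rates of change per round.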

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

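The test on the round 1 lines, the repeats of the slope difference and the exchange of 2 lung lines were chosen after the results they bear on had been seen. In 22 measures of the 4 lung lines, 6 of whole arrays and 16 of named probes, no line's gap to the nearest other line passed Dixon's 95% critical value.

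Slopes per round differed between the routes for 1263 probes in the test of the difference. The count was 85 without DU145-LN4, 437 without DU145-LN2 and 773 without DU145-LN1. Both slopes start from the parental value, so a steady route difference present from the first round also counts. The slope of GI_4504936-S over the lung lines alone was 0.34. Among the probes named for a slope, the lung slope exceeded the lymph node slope by 1.51 log2 units per round for GI_4504936-S (limma adjusted p = 0.00504), by 0.69 for GI_6382070-I (limma adjusted p = 0.0127), by 0.64 for GI_24497582-S (limma adjusted p = 0.0446) and by 0.53 for GI_6382070-A (limma adjusted p = 0.0305). The difference was -1.01 for GI_34147344-S (limma adjusted p = 0.00668) and -0.51 for GI_5453789-S (limma adjusted p = 0.0361), which fell more steeply in the lung route. GI_16418396-S and GI_40254981-S rose in the lymph node route, and their slopes were not shown to differ between the routes (limma adjusted p = 0.304 and 0.704). Without DU145-LN4 none of the 6 differences passed: it was 0.14 for GI_6382070-I, -0.059 for GI_6382070-A and 0.03 for GI_24497582-S, while it was 1.36 for GI_4504936-S, -0.997 for GI_34147344-S and -0.46 for GI_5453789-S. Leaving out other single arrays also ended the call for GI_24497582-S, GI_5453789-S, GI_6382070-I and GI_6382070-A, as did a constant variance prior for the first 2 and a pseudocount of 64 for GI_6382070-A.

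The route difference held for the real grouping alone. Of the 35 splits of the 7 sublines into 3 and 4, only 1, the real one, gave as many as 1209 probes. The highest of the other splits gave 3. Every other split mixes lines of both routes, which widens the spread within its groups. The probes past the threshold thus divide the lines by route. The splits cannot tell an effect of selection from chance divergence of the lines of each route. Over all tested probes the division was partial. Each subline's nearest subline was of its own route, but DU145ivLU1 lay nearer DU145-LN1 (root mean square log2 difference 0.503) than DU145ivLU4 (0.540). At probes called on the lines of later rounds, the median round 1 difference was 0.65 of the later size. That call favours differences steady over the later rounds, so the ratio does not describe the route difference as a whole. Over all tested probes, 365 were 2-fold apart after 1 round and 743 after 4. The numbered rounds read as 1 chain of lines per route, so site of growth, route of injection and the founder cells of that chain were not separated by this design. It may be, as a hypothesis, that part of the route difference was set by the first selection or by the cells that founded each chain.

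DU145ivLU3 departed from both of its neighbours in the lung chain. Its private variance, the covariance across probes of the step into it and the step out of it with the sign turned, was 0.166, against 0.0172 at most for DU145-LN1, DU145-LN2 and DU145ivLU1, and 182 probes lay 2-fold beyond both neighbours, against 17 at most for those 3 lines. Against additive background noise on that array, its ratio to the highest of those 3 lines was 17.5 in the 2216 brightest probes, and against intensity-dependent scaling it was 9.79 after cyclic loess. With lung rounds 3 and 4 exchanged, the line then at round 3 had 0.767 of the highest private variance of those 3 lines, and the lung slope passed for 1543 probes in place of 553. The first value follows from the distances that had shown the departure and the second goes with DU145ivLU3 being farthest from the parental line, so neither is separate evidence for exchanged labels. A state particular to DU145ivLU3, a last line not grown from it or RNA quality may give the same pattern and were not tested. Noise in proportion to signal stays open too, since an earlier comparison of probe pairs, given under the other observations, did not decide on it.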

How the results depend on the processing

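Cyclic loess, the exchange of lung rounds and all repeats of the slope difference were chosen after seeing the data. Lung against lymph node kept a count within 1.5 times of 1209 under quantile normalization, median centring, both filters, both pseudocounts, a constant prior, only these 7 arrays, the rounds block and cyclic loess (1050 to 1258 probes). A 2-fold minimum left 271, and leaving out 1 line gave 291 to 1265. The comparisons with the parental line stayed at 0 probes except 251 for the lymph node route on its own 4 arrays, 0 to 4 when 1 lymph node line was left out and 0 to 3 when 1 lung line was left out. The lymph node slope (28 probes) gave 0 with median centring, the 50th percentile filter or a constant prior and 1 with a pseudocount of 64. It gave 193 over the 3 lymph node lines alone, and 0 to 13 when the parental array or 1 lymph node array was left out. The lung slope (553 probes) gave 205 with a constant prior, 0 over the 4 lung lines alone and 1543 with rounds exchanged. It gave 16 to 624 when the parental array or 1 lung array was left out. The slope difference between the routes (1263 probes) gave 1054 to 1318 under the other normalizations, filters, pseudocounts and prior, 1759 with rounds exchanged, and 85 to 1285 when 1 array was left out. When 1 array was left out, the slope difference turned for GI_6382070-A (-0.059 to 0.65) and for GI_40254981-S, which had not passed (-0.60 to 0.0056). Of the 24 orders of the 4 lung lines, 3 gave at least 553 probes, the highest other being 1543, so the numbered order was not singled out. The correlation of both routes' changes (0.492) was 0.473 with quantile normalization, 0.518 without a filter, 0.468 with the stricter filter, 0.520 and 0.476 with pseudocounts of 1 and 64, and 0.472 to 0.50 when 1 subline was left out. The cause was not tested for any of these changes. Over all repeats of the named probes, 327 values stayed on their side of the threshold, 60 lost a call, 3 gained one and 3 changed direction, all 3 of them slope differences. Values near background limit the differences of dim probes, which move with the pseudocount, and some named probes fell below the dim filter under other settings and have no value there. Set tests of gene lists and their alternatives were not run because probes had no gene names. Lung against lymph node paired by round, with rounds 1, 2 and 4 as the block, gave 1130 probes, and 898 of the 1209 were among them.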

Other observations

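The test of parallel change was planned before its values were computed. The interval after cyclic loess and the comparison of probe pairs were chosen after seeing the data. Some probes that were high in the lymph node lines were also high in the later lung lines. GI_8923166-S read -0.3 in the parental line, 235.3 to 686.4 in the lymph node lines, -26.3 and 25.4 in DU145ivLU1 and DU145ivLU2, and 691.4 and 489.8 in DU145ivLU3 and DU145ivLU4. GI_16418396-S read 48.5 and 117.3 in the first 2 lung lines and 1014.1 and 741.8 in the later ones, and GI_40254981-S 103.6 and 111.7, then 810.2 and 603.1. GI_19747278-A went the other way, at 326.4 in the parental line and 897.9 in DU145ivLU1 but 21.7 to 67.4 in the other lung lines and 22.7 to 34.2 in the lymph node lines.

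This led to the hypothesis that the same probes changed in parallel over the rounds of both routes, tested on differences that share no array. The fourth minus first round differences of both routes correlated across probes at r = 0.176, and at 0.206 in the 2216 brightest probes. In all, 6 pairs of steps were compared between the routes, with r from -0.0028 to 0.242. Single steps over the same rounds hardly correlated, at 0.017 from round 1 to 2 (0.121 in the brightest probes) and -0.0028 from round 2 to 4. The highest value paired unlike steps, DU145-LN1 to DU145-LN2 with DU145ivLU2 to DU145ivLU3. In the fourth minus first differences, 29 probes were 2-fold higher in both routes, where independent lists would share 2.20. Those lower in both numbered 15 against 2.73. But 14 changed in opposite directions against 5.28, so variable probes overlapped in either sense. After cyclic loess r was 0.175 (95% interval over 1000 resamples of probes 0.123 to 0.225), above the bound of 0.1 set for intensity-dependent scaling. No model of scaling gave that bound. Cyclic loess moved the steps by 0.0348 (lymph node) and 0.0323 (lung), root mean square, where the steps measured 0.386 and 0.540. So small a correction could hardly change r, so passing the bound adds nothing by itself. But scaling of the kind cyclic loess removes was small beside the steps. That argues against it as the source of r over the tested probes. A bound of 0.2 first set against scaling could not have been reached from 0.176 and was not used. Probes are not independent, so the interval may be too narrow. The value of 0.176 lay below the 0.2 set for parallel change and above the 0.1 set against it, so that hypothesis stays open.

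As a check on single probes, 61 GI numbers were measured by 2 probes with the endings A and I. Their lung minus lymph node differences correlated at r = 0.543 (95% interval 0.338 to 0.699) across pairs. For the departure of DU145ivLU3 from the mean of its neighbours the correlation was 0.209 (95% interval -0.0457 to 0.437; Spearman's rho 0.0731), within the range of randomly paired probes, whose upper bound was 0.249. For the step from DU145ivLU2 to DU145ivLU3 it was 0.267 (95% interval 0.0168 to 0.487; Spearman's rho 0.202). These values do not decide whether both probes of a pair shared the departure from both neighbours.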
